A study of Arabidopsis thaliana with 37 samples.

How the data were processed

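Total RNA of Arabidopsis seedlings was labelled with biotin as cRNA and hybridised to 37 Affymetrix arrays with 8247 probe sets, 1 sample per array. The deposited values are linear signal intensity per probe set that the authors made with MAS5, per the submitters' processing notes. Its version, scaling target and annotation are not given in the sources used here. The deposited table writes values of at least 1000 with a point between the digit groups. Of its 305139 cells 7913, in 491 probe sets, hold exactly 3 decimals, no other reading exceeds 999.9, and 438 of these probe sets also hold other readings, whose highest has a median of 958.25. Those cells were multiplied by 1000, which gave values up to 8562. Every column belongs to 1 of the 37 samples.

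Groups follow the genotype, background and age in the labels. The 21-day Ler arrays form 2 sets by their names, the first (3 arrays) named like the 9-day Ler series and the second (4 arrays) named like the dcl1-9 arrays. Ler was taken as the main wild type of the ago1 alleles, from background knowledge, and Col as a second, since the labels give no accession for them. The series design text calls the samples biological replicates, and the p-values measure only the spread between these arrays. The groups, tests, fixed gene lists, the rule for named genes and most alternatives were set before the data were examined. Array medians on the log2 scale differed by 1.53, above the limit of 0.3 chosen for scaling, so each array was scaled to a common median. Probe sets above 12.2 (the 40th percentile of all values) on at least 3 arrays were kept, 6112 in number, and log2 was taken after adding 1.2 (the 10th percentile). A group mean under 12.2 is near background, so the size of a difference from it depends on the constant added. The table holds 0 Affymetrix control probe sets.

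One limma model (3.58.1 in R 4.3.3, lmFit, contrasts.fit and eBayes with trend) held all 37 arrays with a mean per group and no covariate. A probe set was called at a Benjamini-Hochberg adjusted p under 0.05 within its comparison, and differences between effects were tested as contrasts of the same model. Tables and figures used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9. On simulated data with 50 probe sets changed at each fold among 6112, 94, 90, 96, 86 and 96% of 4-fold changes and 40, 48, 34, 30 and 50% of 2-fold changes were recovered, for ago1-10 at 9 and 21 days, ago1-11 at 9 and 21 days and dcl1-9, with 8, 5, 6, 10 and 2 unchanged probe sets called. The simulated noise was normal, independent and of the same spread in every group. The rates therefore do not cover groups whose own spread differs from the shared one.

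Of the probe sets 3794 have 1 gene in the platform annotation, 70 have several and 4383 are not listed there and stay unnamed here. Symbols were updated through the TAIR10.1 gene table, where 3784 matched 3592 loci. Of the 6112 tested, 2701 have 1 gene and 523 a symbol other than the locus. For each main comparison the text names, outside the fixed lists, the 10 highest and 5 lowest differences among called 1-gene probe sets whose mutant arrays all lie on one side of all wild-type arrays, and the members of the fixed gene lists with the smallest adjusted p, up to 4 per list. Other comparisons name 3 and 3. Other genes named (among them CCS in the closing part, AT2G44140 at 21 days, and members of the lists added later) were chosen after their values were seen.

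Fixed lists held 317 genes, of which 20 are annotated and 19 measured, so many lists had no measured gene. A list need not hold every gene of its class, so counts of microRNA targets are counts of listed targets. Those with at least 3 were microRNA and TAS3 targets (5), the same without HD-ZIP genes (4), photosynthesis (3) and cold, drought and ABA (3). PHV, SE, YAB3, GH3.3, WES1, THI2.1, DFR, AT1G53540 and AOP3 stood for smaller lists. A further 11 lists were formed from the annotated symbols before any comparison was computed. They cover the cell wall, photosynthesis and chlorophyll, LEA with cold and drought, auxin, WRKY and defence, glycosyltransferases, serine carboxypeptidases, MADS box, pollen with anther and flower, ATG8, and defensins. A locus was represented by its brightest probe set. Camera was run with a preset correlation of 0.01 and with an estimated one, and fry beside it, and p-values were adjusted over all 75 tests. Of these 10 passed with the preset and 2 with the estimated correlation, both in dcl1-9. Fry tests each list on its own and passed 16, of which 7 did not pass camera, while 1 list passed camera alone.

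Alternatives set beforehand were quantile normalization, centred log2 medians, a pseudocount of 1, no filter, a model with only the groups compared, plain probe sets only, each array left out in turn, the other Ler set, strain codes and replicate labels. Added after the data were seen were scaling to a trimmed mean, a pseudocount of 16, the point between digit groups read as a decimal point, a run without 7 arrays that correlated best with another genotype, and a grouping of the 21- and 35-day ago1-10 arrays by the number in their sample titles. Scaling to a trimmed mean moved the median of all probe sets by more than 0.1 in the 9-day ago1-11 (0.12), 21-day ago1-10 against Col (0.12) and Ler against Col (0.13) comparisons, the age effect in ago1-11 (-0.19) and the ago1-11 against dcl1-9 difference (-0.11). Arrays differed in brightness, with trimmed mean signals from 37.3 to 119.8, and correlated within groups at 0.865 to 0.972. Sequences of the probes were not used here.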

Results

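RNA from whole seedlings of Arabidopsis thaliana was measured on 37 one-colour arrays that carry 8247 probe sets. The seedlings were wild type, carried 1 of 2 alleles of the ARGONAUTE1 gene (ago1-10 or ago1-11), or carried the dcl1-9 allele of DICER-LIKE1, also called caf. AGO1 is the main slicing protein of the plant microRNA pathway and DCL1 makes most of its microRNAs. At 9 days there were 3 Ler, 3 Col, 4 ago1-10 and 4 ago1-11 arrays. At 21 days there were 3 arrays of a first Ler set, 4 of a second Ler set, 3 Col, 3 ago1-10, 3 ago1-11 and 4 dcl1-9 arrays, and ago1-10 was also measured on 3 arrays at 35 days. The number of arrays limits the precision. Of the probe sets, 6112 were bright enough to test, and 2701 of these match 1 named gene. Neither AGO1 nor DCL1 has a named probe set here, so the mutated genes themselves were not followed. Values after a gene are log2 differences, mutant minus wild type, and signals are scaled array values with their SD. Where a group mean lies under 12.2, the filter value, the size of the log2 difference depends on the 1.2 added before the log and is uncertain. Of 48 such calls among the genes selected in the main comparisons, 41 held with 16 added.

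The first comparison asks which transcripts differ in 9-day seedlings of the ago1-10 allele. Replicate 4 of ago1-10 carries strain code MR49 and the other arrays MR44, and all are taken here as replicates. With the MR44 arrays only, 70 selected probe sets kept their status and 0 changed it. A ribosomal protein L7 family gene, AT2G44120, fell from 618 ± 106 in 3 Ler arrays to 5.52 ± 3.75, near background, in 4 ago1-10 arrays (adjusted p = 1.4e-16). The difference was -6.68 with 1.2 added and -4.88 with 16 added, so the fall is given as at least 4.88. AT2G44140, the next gene by start position, fell with it (-3.69, adjusted p = 1.0e-08). Other genes that fell were the expansin gene EXPA8 (-4.08, 25 ± 14.1 against 428 ± 183), the glycine-rich protein gene AT2G05540 (-4.16) and EXGT-A3 (-2.45), while the cell wall list had 2 of 14 genes fallen and did not pass (adjusted p = 0.352). The microRNA target ARPN, which encodes plantacyanin, rose from 30.1 ± 4.50 to 169 ± 67.1 (2.38, adjusted p = 4.4e-05). Altogether 979 probe sets changed, 393 higher and 586 lower, and 250 and 375 of these changed at least 2-fold.

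Among the other genes that rose in 9-day ago1-10 seedlings, Hsp70-2 had the largest difference outside the fixed lists (3.44, adjusted p = 0.0015, or 1.44 with 16 added). It was followed by AT3G47342 (2.78), the PR-1-like gene AT4G33720 (2.63, adjusted p = 0.032), the peroxidase gene AT4G36430 (2.59), AT2G42060 (2.58) and AT2G34357 (2.53). AT2G35820 (2.44), CCOAMT (2.41), AT4G26365 (2.40) and the beta-1,3-glucanase-like gene AT4G16260 (2.37, 1350 ± 519 against 275 ± 170) completed the 10 highest outside the fixed lists. The fixed-list gene ARPN stood above AT4G16260 on all 3 of its probe sets (3.33, 2.58 and 2.38). The Ler means of Hsp70-2, AT3G47342, AT2G42060, AT2G34357, CCOAMT and AT4G26365 lay under 12.2. With 16 added none of these genes stood above 1.44, so their sizes and places in the order depend on the constant added. AT4G16260, placed last, was bright in both groups. The thionin gene THI2.2 fell by 3.80. Cold-induced genes were split, since COR15B rose from 101 ± 50.9 to 460 ± 178 (2.24, adjusted p = 4.0e-05) while COR47 (-1.28) and KIN2 (-1.11) fell. The autophagy gene ATG8E fell (-2.21), and so did the zinc finger gene ZAT7 (-2.38) and the glycosyltransferase gene UGT72E1 (-1.90), while the osmotin gene OSM34 rose (1.98). The auxin-conjugating enzyme gene GH3.3 also fell (-1.72, adjusted p = 0.046). Every gene named as risen or fallen had all 4 mutant arrays on one side of all 3 Ler arrays, which the choice by size required.

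Some photosynthesis genes fell in 9-day ago1-10 seedlings. Thioredoxin f2 (TRXF2, -1.87), hydroxypyruvate reductase (HPR, -1.25), LHB1B2 (-1.24), PSAE-1 (-1.10), LHCB4.1 (-1.09) and Rubisco activase (RCA, -0.84) fell, whereas LHCB4.3 rose (1.59). Of 24 measured photosynthesis and chlorophyll genes 10 fell and 1 rose (median -0.72, camera adjusted p = 0.0011, and adjusted p = 0.612 with an estimated correlation). The 3 measured genes of the smaller list fixed beforehand, LHCB4.1, RCA and PSAE-1, all fell, also adjusted over the list alone, with a camera adjusted p of 0.0049 (adjusted p = 0.298 with an estimated correlation). Under quantile normalization RCA stood at -0.22, LHCB4.1 at -0.39 and PSAE-1 at -0.44, none of them called, and 4 genes of the longer list fell, with a median of -0.32.

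Of the 5 measured genes on the microRNA target list ARPN rose at 9 days. The F-box gene LCR (0.65), the ATP sulfurylase genes APS3 (-0.22) and APS4 (-0.08) and the HD-ZIP gene PHV (-0.24) did not pass. The 5 had a mean of 0.50 and a median of -0.08. That median turned positive with quantile normalization (0.02) or a trimmed mean (0.01), and camera gave an adjusted p of 0.487 (Up). The 4 of them outside the HD-ZIP family had an adjusted p of 0.336, and 0.0426 by fry. SE (0.14), YAB3 (-0.56), WES1 (0.47), THI2.1 (0.79), DFR (-0.62), the heat shock gene AT1G53540 (-0.70) and AOP3 (0.23) did not pass either. Leaving out Ler replicate 3 lowered the count of changed probe sets to 562 and leaving out Ler replicate 2 lowered it to 645. The AT4G33720 call ended without ago1-10 replicate 1 or 2 or Ler replicate 3, and without Ler replicate 1 (adjusted p = 0.150). The AT4G26365 call ended without ago1-10 replicate 2 or Ler replicate 1, and without Ler replicate 2 (adjusted p = 0.127). KIN2 was lost without Ler replicate 2 (adjusted p = 0.125), and GH3.3 on leaving out any array but ago1-10 replicate 4 (adjusted p up to 0.209).

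**Figure D1:**
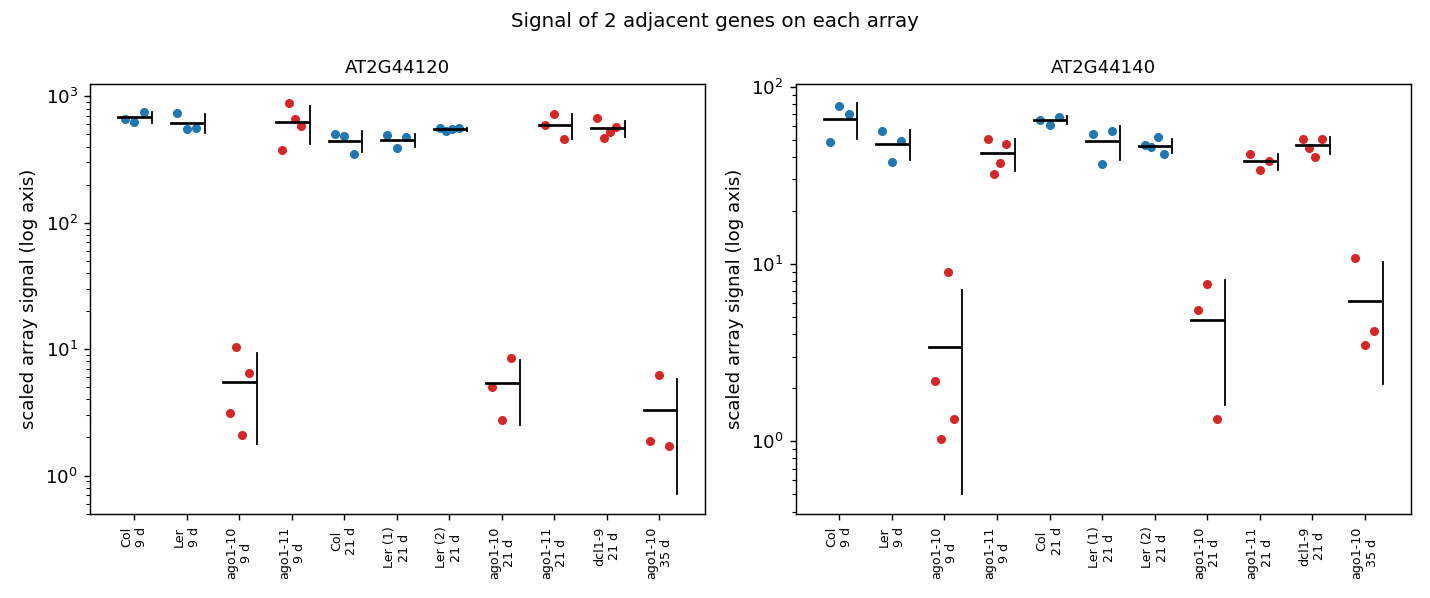
Scaled array signal on a log axis of AT2G44120 and AT2G44140 on each array of the 11 groups, with blue points for wild type, red points for mutants, horizontal lines for means and vertical bars for SD. All ago1-10 arrays lie far below every other array, with AT2G44120 means of 5.52, 5.39 and 3.28 at 9, 21 and 35 days against 618 in 9-day Ler.

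At 21 days the ago1-10 comparison, against the first Ler set, asks the same question in older plants. The largest rise outside the fixed lists was that of AT4G33720, from 85.8 ± 111 to 901 ± 178 (4.56, adjusted p = 0.00049, with 3.58 on a second probe set). Without Ler replicate 1 the first probe set stood at 3.26 (adjusted p = 0.013), so the size of this rise rests partly on that array. The peroxidase gene AT5G06730 rose from 5.41 ± 4.04 to 127 ± 92.3 (4.32, or 2.56 with 16 added), and the chitinase genes AT2G43590 (4.12) and ChiC (3.97) rose as well. AT4G16260 reached 2158 ± 299 against 165 ± 88.2 (3.81, adjusted p = 2.1e-05). In all 1315 probe sets changed, 611 higher and 704 lower, with 439 and 495 of them at least 2-fold. The sample title of replicate 3 (x44-3B) carries the number 3, while the other 21-day arrays with numbered titles carry 2. With that array exchanged for 35-day replicate 1 (x49-2A) 1880 probe sets changed, 934 higher and 946 lower, and of 72 probe sets selected 66 kept their status, 6 gained a call and 0 lost one.

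Other genes that rose in 21-day ago1-10 plants were the berberine-bridge-like gene AT1G30760 (3.99, adjusted p = 1.3e-06), AT1G65500 (3.85), the alpha-amylase gene AMY1 (3.75, or 1.87 with 16 added, 58.9 ± 26.7 against 3.97 ± 4.16) and AT1G78860 (3.73). AT2G44120 fell again (-6.20, or -4.46 with 16 added, 5.39 ± 2.87 against 454 ± 53.4) and AT2G44140 fell by 3.22. AT2G20870 fell by 5.24 and 4.94 on its 2 probe sets, EXPA8 fell by 3.78 and AT2G39850 by 3.52. OSM34 rose by 2.86, the drought-induced gene DI21 by 2.75 and the defensin genes LCR67 by 3.38 and PDF2.1 by 1.78. THI2.2 (-3.25) and the auxin glucosyltransferase gene IAGLU (-2.02) fell, as did UGT73B1 (-1.91) and UGT73C1 (-2.04), while UGT72E3 (1.99) and WRKY53 (1.98) rose. The leaf polarity gene YAB3 fell from 82.4 ± 13.6 to 31.7 ± 4.3 (-1.34, adjusted p = 0.0007). Every gene named as risen or fallen had all 3 ago1-10 arrays on one side of all 3 Ler arrays, which the choice by size required.

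Of the listed microRNA targets ARPN and APS4 rose in 21-day ago1-10 plants. ARPN went from 16.8 ± 7.13 to 110 ± 63.6 (2.51, adjusted p = 4.5e-05) and APS4 from 119 ± 28.7 to 528 ± 174 (2.11, adjusted p = 2.8e-06). LCR (0.51), PHV (0.35) and APS3 (0.35) were positive without passing. Of these 5 targets 2 rose, the same number as adjusted over the list alone, with a median of 0.51 and a camera adjusted p of 0.014 (adjusted p = 0.240 with an estimated correlation). The 4 targets without PHV gave a median of 1.31 and an adjusted p of 0.010 (adjusted p = 0.128 with an estimated correlation).

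Of 24 photosynthesis and chlorophyll genes in 21-day ago1-10 plants 18 fell and 1, LHCB4.3 (1.44), rose (median -1.27, camera adjusted p = 9.9e-10, and adjusted p = 0.298 with an estimated correlation). The fallen genes included PSAN (-1.80), HPR (-1.80), TAPX (-1.63), PSB27 (-1.60), TROL (-1.56), PORB (-1.53), TRXF2 (-1.46), NdhS (-1.41), NTRC (-1.39), PRK (-1.30) and SBPASE (-1.24). LHCB4.1 (-1.31), RCA (-0.92) and PSAE-1 (-1.35), the list fixed beforehand, all fell, also adjusted over the list alone, with an adjusted p of 0.0049 (adjusted p = 0.298 with an estimated correlation, and 0.0846 with quantile normalization). Quantile normalization left RCA at -0.35 and uncalled. SE (-0.04), GH3.3 (-0.78), WES1 (-0.84), THI2.1 (-0.13), DFR (0.22), AT1G53540 (0.40), COR15B (-0.93), KIN2 (-0.65), COR47 (0.20) and AOP3 (-0.10) did not pass. Leaving out ago1-10 replicate 1 lowered the count of changed probe sets to 782 and ended the calls of UGT73B1 (adjusted p = 0.156) and LTI30 (1.57, adjusted p = 0.113). Single Ler omissions ended those of the second AT4G33720 probe set (0.0783 without replicate 1), WRKY53 (0.120 without replicate 3) and UGT72E3 (0.0872 without replicate 3). LCR67 was lost without ago1-10 replicate 2 (0.0963) and UGT73C1 without ago1-10 replicate 3 (0.0533). With the second Ler set as wild type 1519 probe sets changed, all 15 probe sets named by size kept their calls, KIN2 turned to 1.55, and the fall of AT2G20870 shrank to 2.35 and 1.71.

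**Figure D2:**
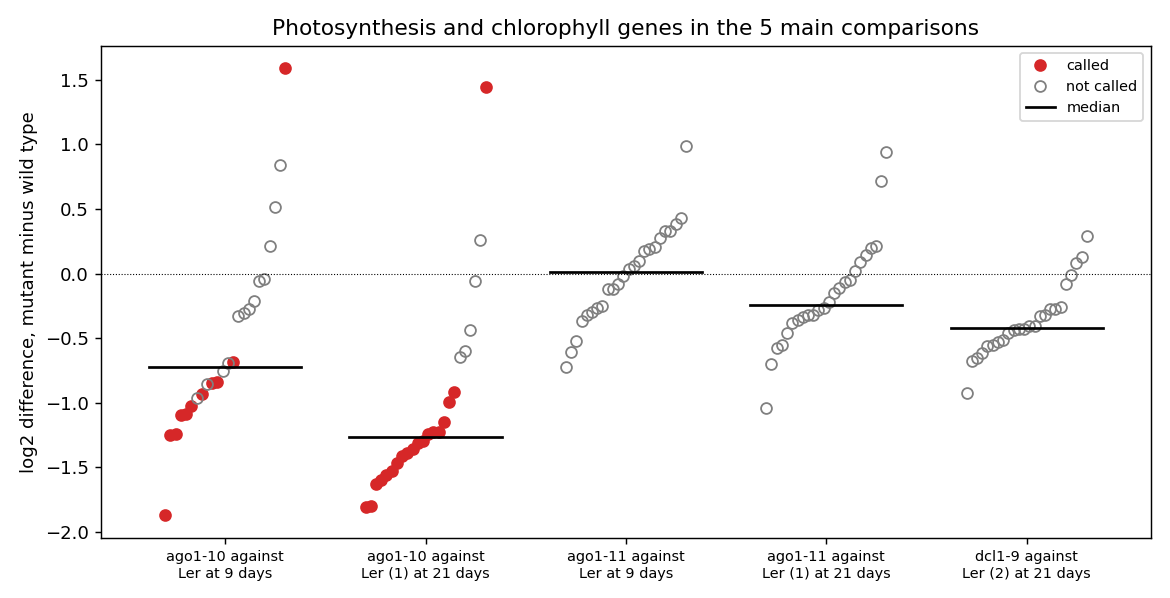
Log2 difference, mutant minus wild type, of the 24 measured photosynthesis and chlorophyll genes in the 5 main comparisons, with filled points for called genes, open points for the others and lines at the medians. The median was -0.72 and -1.27 in ago1-10 at 9 and 21 days and lay between 0.01 and -0.42 in the other comparisons. The 21-day medians depend on the Ler set. With the other set, not shown, they were -0.98 in ago1-10, 0.15 in ago1-11 and -0.74 in dcl1-9.

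The ago1-11 comparison at 9 days asks whether a second allele changes the same transcripts. Its 4 arrays carry 4 strain codes (MR51, MR53, MR54 and MR57), taken here as replicates of 1 genotype. The cold-induced gene COR15B rose from 101 ± 50.9 to 487 ± 83.7 (2.39, adjusted p = 4.6e-05). The ACC oxidase-like gene AT1G12010 rose from 1.41 ± 0.239 to 17.2 ± 8.72 (2.69, adjusted p = 0.0044), but with 16 added it stood at 0.89 and was not called (adjusted p = 0.061). AT2G35820 (2.57) and CCOAMT (1.80) rose, as they did in ago1-10. AT4G33550 fell from 153 ± 13.8 to 29.0 ± 5.55 (-2.37, adjusted p = 1.5e-06) and AT1G23130 from 394 ± 87.0 to 70.6 ± 14 (-2.46). In total 287 probe sets changed, 129 higher and 158 lower, with 96 and 116 at least 2-fold. The split was 144 higher and 116 lower with quantile normalization, and 189 and 111 scaled to a trimmed mean, which shifted all probe sets by 0.12.

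AT2G44290 (2.14), AT2G28490 (2.09), AT4G27280 (1.93), AT4G18820 (1.82), AT1G78820 (1.64), AT2G19390 (1.64) and the splicing factor gene ATU2AF35A (1.58, adjusted p = 5.3e-05) also rose in 9-day ago1-11 seedlings. AT1G09500 fell by 2.71 and 2.66 on its 2 probe sets (not called with 16 added, adjusted p = 0.119 and 0.259) and AT2G34930 fell by 2.2. WRKY22 (1.08) rose and UGT72E1 (-1.79) and UGT74B1 (-0.91) fell. All of these genes had all 4 ago1-11 arrays on one side of all 3 Ler arrays, which the choice by size required. Of 19 glycosyltransferase genes 4 fell and 0 rose (median -0.60, camera adjusted p = 0.018, and adjusted p = 0.298 with an estimated correlation). Of the 4, UGT73C1 lost its call on 6 of 7 omissions and UGT84A3 on 5 (adjusted p up to 0.183 and 0.301, without Ler replicate 3), and 2 genes fell with centred log2 medians or a trimmed mean and 3 with quantile normalization. The listed microRNA targets did not pass, at 0.61 for ARPN, 0.72 for LCR, 0.06 for PHV, -0.08 for APS4 and -0.41 for APS3. Neither did their list of 5 (adjusted p = 0.748) or the 4 without PHV (adjusted p = 0.748). COR47 (-1.09, adjusted p = 0.056), KIN2 (-0.83), YAB3 (0.48), SE (0.33), GH3.3 (-1.19), WES1 (0.53), THI2.1 (0.30), DFR (-0.85), AT1G53540 (-0.04) and AOP3 (-0.75) did not pass.

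Of 24 photosynthesis genes in 9-day ago1-11 seedlings 0 were called (median 0.01, mean -0.01, Down, adjusted p = 0.983). With quantile normalization or a trimmed mean 1 was called higher, and leaving out 1 ago1-11 array called LHCB4.3 (1.36, without replicate 4) or LHB1B2 (-0.83, without replicate 1). LHCB4.1 stood at -0.32, RCA at -0.37 and PSAE-1 at -0.52 (list of 3, 0 over all probe sets and 0 adjusted over the list alone, adjusted p = 0.262). The count of changed probe sets rested on the Ler arrays, since it was 505 without Ler replicate 1, 94 without Ler replicate 2 and 85 without Ler replicate 3. Of 15 probe sets named by size, 7 lost their call on some omission. The highest adjusted p was 0.200 for AT2G28490 and for AT4G18820, 0.174 for AT1G78820 and 0.182 for the weaker AT1G09500 probe set, all without Ler replicate 3, which also ended the call of the other AT1G09500 probe set (0.0539). It was 0.113 for AT2G34930 without Ler replicate 2 and 0.0910 for AT2G44290 without Ler replicate 1.

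At 21 days ago1-11 was compared with the first Ler set. The beta-glucosidase gene BGLU28 rose from 0.903 ± 0.160 to 35.7 ± 18.6 (adjusted p = 0.00026). Its Ler signal is below the 1.2 added, so its log2 difference of 4.01 depends on that constant, and the rise is given as at least 1.55, its value with 16 added. The brassinosteroid-linked gene EXO rose from 108 ± 10.7 to 511 ± 44.8 (2.23, adjusted p = 0.0013), and the methionine sulfoxide reductase gene MSRB5 from 39.4 ± 11.3 to 183 ± 69.3 (2.13, adjusted p = 0.00016). The sulfate-assimilation gene APS4, a microRNA target, rose from 119 ± 28.7 to 283 ± 65.4 (1.25, adjusted p = 0.011). IAGLU fell (-2.15, adjusted p = 1.9e-05). In total 170 probe sets changed, 100 higher and 70 lower, with 93 and 64 at least 2-fold.

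The chitinase genes AT2G43620 (3.80, adjusted p = 0.042) and AT2G43590 (2.89) also rose in 21-day ago1-11 plants, with AT1G12010 (2.96, or 1.09 with 16 added), AT2G42360 (2.59), AT1G54010 (2.11), AT1G22900 (2.09), AT3G15356 (1.96) and DI21 (1.73). AT2G20870 fell by 3.08 and 2.66 on its 2 probe sets, EXPA8 fell by 2.43, UGT73C1 by 2.27 and UGT73B1 by 2.15. All genes named as changed had all 3 ago1-11 arrays on one side of all 3 Ler arrays, which the choice by size required. ARPN stood at 1.06 (adjusted p = 0.173), LCR at 0.17, PHV at 0.04 and APS3 at 0.02, so that all 5 targets were positive without their list passing (1 called, 2 adjusted over the list alone, adjusted p = 0.193). The 4 without PHV had an adjusted p of 0.131, and 0.0185 by fry. LHCB4.1 (-0.11), RCA (0.02), PSAE-1 (-0.07), YAB3 (0.66), SE (0.17), GH3.3 (0.82), WES1 (-0.90), THI2.1 (-0.30), DFR (-0.28), AT1G53540 (0.29), COR15B (-0.19), KIN2 (-0.46), COR47 (-0.34) and AOP3 (0.22) did not pass. Photosynthesis genes gave adjusted p = 0.849 for the list fixed beforehand and 0.280 for the longer list.

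The 21-day ago1-11 result rested on few arrays and on the choice of Ler set. The count was 68, 76 and 273 without Ler replicates 3, 1 and 2, and 71 and 101 without ago1-11 replicates 1 and 2. Of 15 probe sets named by size, 4 kept their call on every omission, those of BGLU28, EXO, MSRB5 and 1 of the AT2G20870 probe sets. The others reached adjusted p of 0.327 for AT1G54010, 0.239 for AT2G43620, 0.192 for EXPA8, 0.179 for UGT73B1, 0.0898 for AT3G15356, 0.0881 for UGT73C1, 0.0626 for the other AT2G20870 probe set and 0.0568 for AT1G12010, all without ago1-11 replicate 1. Without that array APS4 (0.0885) and DI21 (0.280) were lost too, and APS4 also without Ler replicate 1 (0.0806) or 3 (0.0514). AT2G43590 reached 0.210 and AT1G22900 0.0697 without Ler replicate 1, and AT2G42360 0.0968 without Ler replicate 3. Against the second Ler set 705 probe sets changed, 403 higher and 302 lower. ARPN was then called (2.26, adjusted p = 0.00015), BGLU28, EXO, MSRB5 and APS4 (1.65) kept their calls, and EXPA8 (-0.75), AT2G42360 (1.07), AT1G54010 (1.45), AT1G22900 (0.82), AT3G15356 (0.56) and AT2G20870 (0.15 and 0.23) lost theirs.

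The dcl1-9 comparison at 21 days, against the second Ler set, asks which transcripts differ when microRNA production is impaired. ARPN rose from 6.38 ± 1.33 in 4 Ler arrays to 32.1 ± 8.96 in 4 dcl1-9 arrays (2.11, adjusted p = 0.00088), and its other probe sets rose by 2.51 and 2.97. With 16 added the first stood at 1.09 (adjusted p = 0.048). CCS, the gene of the copper chaperone of superoxide dismutase, rose from 76.7 ± 32.6 to 261 ± 49.3 (1.81, adjusted p = 0.00088). AT4G33720 rose by 4.24 and 4.07 on its 2 probe sets (256 ± 118 against 18.5 ± 13.5, adjusted p = 0.0034). The jacalin lectin genes JAL31 (1.76) and JAL34 (1.52, 209 ± 29.0 against 75.6 ± 26.0) and the beta-glucosidase gene BGLU21 (2.53, 565 ± 180 against 115 ± 62.8) rose as well. In total 48 probe sets changed, 39 higher and 9 lower, with 37 and 6 at least 2-fold. With only the groups compared in the model the count was 285, 156 higher and 129 lower.

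The peroxidase gene AT5G64100 (2.56, 175 ± 74.8 against 26.9 ± 5.82), AT4G12545 (2.62), AT2G22590 (2.16) and AT2G41800 (1.5) rose in dcl1-9, of which the last 2 were not called with 16 added (adjusted p = 0.0748 and 0.358). The allantoate amidohydrolase gene AAH (-1.25) and AT4G36530 (-0.99) were the only 1-gene probe sets lower. Each of these genes had all 4 dcl1-9 arrays on one side of all 4 Ler arrays, which the choice by size required. The listed microRNA targets were higher as a group, with LCR at 0.90, APS4 at 0.82, PHV at 0.33 and APS3 at 0.01 beside ARPN. All 5 were positive (median 0.82), 1 was called, 3 adjusted over the list alone, and the list passed camera with an adjusted p of 0.00015 (adjusted p = 0.029 with an estimated correlation). The 4 without PHV had the same adjusted p of 0.00015 (adjusted p = 0.019 with an estimated correlation, 3 called adjusted over the list alone). Of 24 photosynthesis and chlorophyll genes 0 were called (median -0.42, camera adjusted p = 2.3e-05, but adjusted p = 0.439 with an estimated correlation and 0.130 by fry). LHCB4.1 (-0.28), RCA (-0.26) and PSAE-1 (-0.32) did not pass as a list (adjusted p = 0.262), and their median of -0.28 moved to 0.00 with quantile normalization. SE (0.35), YAB3 (-0.19), GH3.3 (-0.53), WES1 (0.05), THI2.1 (-0.27), DFR (1.12), AT1G53540 (0.41), COR15B (0.68), KIN2 (0.19), COR47 (0.15) and AOP3 (-0.83) did not pass.

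The dcl1-9 result depended on the Ler set and on the model. Against the first set 336 probe sets changed, 145 higher and 191 lower, and ARPN (0.91, adjusted p = 0.178), CCS (0.43), AT4G33720 (1.63 and 2.41), AT5G64100 (1.28), BGLU21 (1.12), AT4G12545 (1.05), AT2G22590 (1.05) and AT2G41800 (0.13) were not called, while JAL31 (1.52), JAL34 (1.14), AAH (-1.26) and AT4G36530 (-0.92) were. KIN2 reversed to -2.02 (adjusted p = 0.00012) and IAA18 to 0.96 (adjusted p = 0.030), both called against that set, and RCA (-0.75) and PSAE-1 (-0.94) gained calls. All 5 targets stayed positive against that set (median 0.41, adjusted p = 0.0495, and adjusted p = 0.268 with an estimated correlation). Of 24 photosynthesis and chlorophyll genes 7 were lower and 0 higher against that set. Their median was -0.74 (camera adjusted p = 1.2e-06, and adjusted p = 0.299 with an estimated correlation). Among the omissions the count was 16, 22 and 19 without dcl1-9 replicates 1, 3 and 4, and 20, 30 and 22 without Ler replicates 2, 3 and 4. The calls of ARPN, CCS and both AT4G33720 probe sets held on every omission, and those of the 9 other probe sets named by size ended on some. Their adjusted p reached 0.230 for AT4G12545, 0.203 for BGLU21 and for AT2G41800, 0.153 for JAL31 and 0.115 for JAL34 without Ler replicate 2. It reached 0.188 for AT2G22590 and 0.0784 for AT5G64100 without dcl1-9 replicate 4, 0.204 for AAH without replicate 1 and 0.275 for AT4G36530 without replicate 3.

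**Figure D3:**
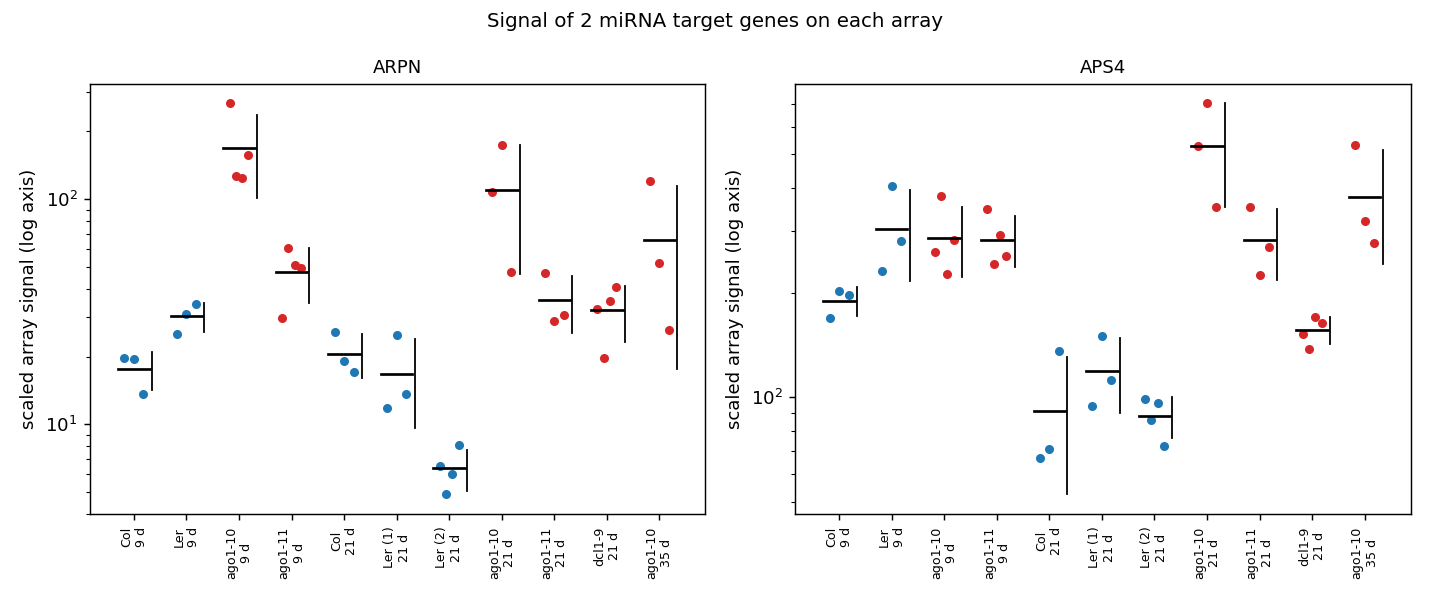
Scaled array signal on a log axis of the microRNA targets ARPN and APS4 on each array of the 11 groups, with blue points for wild type, red points for mutants, horizontal lines for means and vertical bars for SD. ARPN averaged 169 in 9-day ago1-10 against 30.1 in Ler, and 32.1 in dcl1-9 against 6.38 in the second and 16.8 in the first Ler set.

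The remaining gene lists did not pass camera in any main comparison as planned. In the order ago1-10 at 9 and 21 days, ago1-11 at 9 and 21 days and dcl1-9, cell wall genes had adjusted p of 0.352, 0.778, 0.345, 0.338 and 0.516. At 21 days in ago1-10 their median was 0.04 with a mean of -0.23, and the median turned negative with quantile normalization (-0.03) or centred log2 medians (-0.01). The fixed cold, drought and ABA list gave 0.828, 0.557, 0.983, 0.487 and 0.336, with all 3 genes called adjusted over the list alone in both alleles at 9 days and 0 in the rest. In ago1-11 at 9 days its median was -0.83 and its mean 0.16. The longer LEA, cold and drought list gave 0.858, 0.745, 0.849, 0.843 and 0.489, with a median of -0.19 and a mean of 0.03 in ago1-11 at 21 days. Auxin genes gave 0.543, 0.280, 0.516, 0.279 and 0.487, but passed fry, which tests a list on its own, as lower in 21-day ago1-10 (0.0014) and ago1-11 (0.029). Of the fixed lists with only 1 or 2 measured genes, adjusted over the list alone, GH3.3 passed in 9-day ago1-10, YAB3 in ago1-10 at both ages and in 21-day ago1-11, and DFR and AOP3 passed in dcl1-9.

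WRKY and defence genes gave adjusted p of 0.785, 0.352, 0.983, 0.745 and 0.743 in the same order. Their medians and means differed in sign in ago1-10 at 9 days (0.08 and -0.06), ago1-11 at 9 days (0.00 and -0.10) and dcl1-9 (-0.08 and 0.09), and in ago1-11 the median turned negative with quantile normalization at 9 (-0.01) and 21 days (-0.03). Glycosyltransferase genes gave 0.750, 0.983, 0.131 and 0.288 outside 9-day ago1-11, with medians and means of 0.22 and -0.02 in 21-day ago1-10. Serine carboxypeptidase-like genes gave 0.785, 0.745, 0.839, 0.743 and 0.543, with a median of 0.17 and a mean of -0.07 in 9-day ago1-10. MADS box genes gave 0.983, 0.983, 0.487, 0.138 and 0.352, and passed fry in 21-day ago1-11 (0.011, Up). In ago1-10 their medians of -0.03 and -0.03 and means of 0.03 and 0.09 differed in sign, and the 9-day median was 0.05 scaled to a trimmed mean. Pollen, anther and flower genes gave 0.748, 0.877, 0.745, 0.828 and 0.745, with a median of 0.15 and a mean of -0.13 in 9-day ago1-10 and of -0.02 and 0.29 in 21-day ago1-11. ATG8 genes gave 0.312, 0.750, 0.487, 0.745 and 0.742. Defensin genes gave 0.613, 0.155, 0.984, 0.0556 and 0.336, and passed fry in 21-day ago1-10 (0.011, Up) and ago1-11 (0.026, Up). They passed camera in 21-day ago1-10 with quantile normalization (0.0467) and in 21-day ago1-11 without a filter (0.0407) or scaled to a trimmed mean (0.0270). With the other Ler set at 21 days defensin genes passed in ago1-10 (0.0310) and ago1-11 (0.0139), cell wall genes in ago1-11 (0.0310) and auxin genes in both alleles (0.0485), while the fixed photosynthesis list did not pass in ago1-10 (0.113) and passed in dcl1-9 (0.0051). The list tests with the other Ler set were added after the main results were seen. None of the passes with that set held with an estimated correlation, where the lowest adjusted p among them was 0.208. The estimated correlation was not run together with quantile normalization, the trimmed mean, the missing filter or the grouping by title number.

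**Figure D4:**
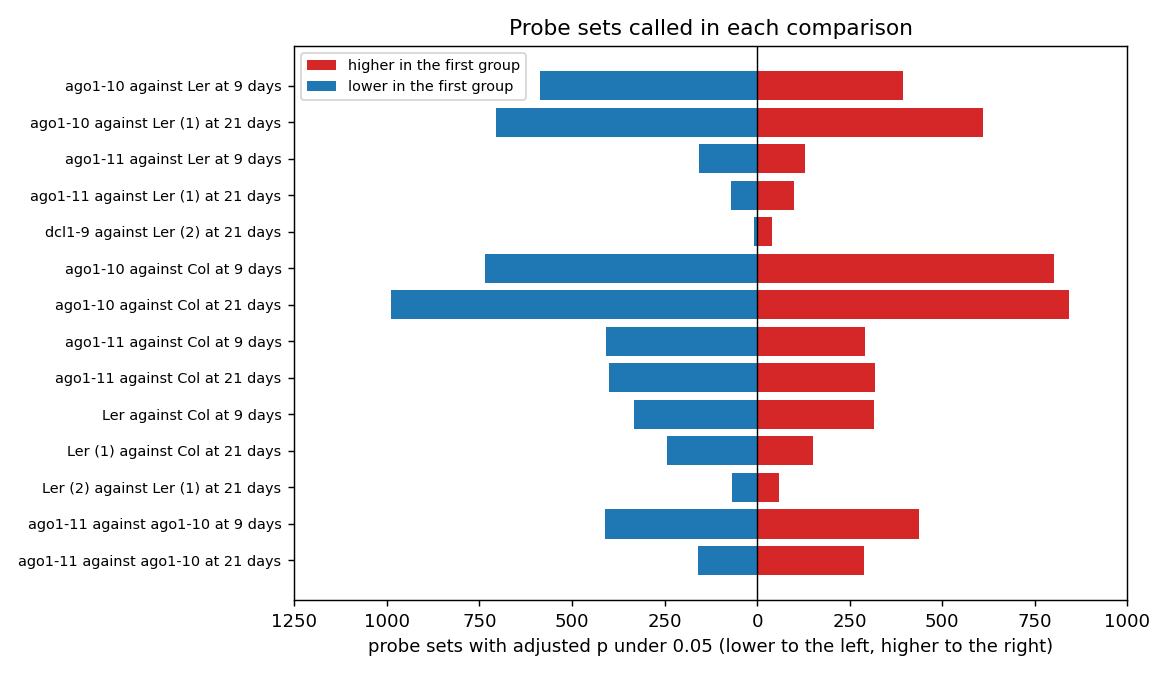
Number of probe sets with an adjusted p under 0.05 in each of 14 comparisons, higher in the first group to the right and lower to the left. The main comparisons called between 48 probe sets (dcl1-9) and 1315 (ago1-10 at 21 days). With only the groups compared dcl1-9 called 285, more than ago1-11 at 9 (95) and 21 days (70). The order of the counts thus depends on the groups from which the spread is taken. In 9-day ago1-11 the split was 144 higher and 116 lower with quantile normalization and 189 and 111 scaled to a trimmed mean.

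The ago1 alleles were also set against Col, because the labels do not give their accession. AT2G13770 was higher in ago1-10 at 9 days (5.98, 106 ± 21.0 against 0.477 ± 0.146) and at 21 days (5.30) and in ago1-11 at both ages (5.28 and 5.21), but it was also higher in Ler than in Col (4.90 at 9 and 4.72 at 21 days). AT4G33720 was higher in ago1-10 by 5.32 at 9 days and by 7.03 and 6.82 at 21 days, and in ago1-11 by 3.97 and 3.52 and by 5.73 and 5.57. AT2G43620 was higher in 9-day ago1-10 (5.22). AT2G44120 was lower in ago1-10 at 9 (-6.84) and 21 days (-6.16). AT2G05540 was lower in 9-day ago1-10 (-6.68) and 21-day ago1-11 (-4.62). Also lower were AT2G25450 in 9-day ago1-10 (-6.54) and ago1-11 (-6.24), AT5G49440 in ago1-11 (-6.27 and -4.65), UGT73B1 in 9-day ago1-11 (-4.86), AT1G62510 in 21-day ago1-10 (-5.30) and AT1G61190 in both alleles at 21 days (-5.16 and -5.10).

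Against Col 1536 (802 higher, 734 lower) and 1833 (843 and 990) probe sets changed in ago1-10 at 9 and 21 days, and 698 (291 and 407) and 718 (318 and 400) in ago1-11. Scaled to a trimmed mean, the 21-day ago1-10 split was 1059 higher and 817 lower, with all probe sets shifted by 0.12. Called the same way against Ler and Col were 544 (234 higher, 310 lower) and 945 (423 and 522) probe sets in ago1-10, which is 55.6% and 71.9% of the calls against Ler, and 95 (43 and 52) and 106 (62 and 44) in ago1-11, or 33.1% and 62.4%. Opposite calls numbered 17, 9, 8 and 1. For 9-day ago1-11 the split of probe sets called against both was 58 and 41 scaled to a trimmed mean.

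The wild types differed among themselves. Ler had more AT4G33720 (3.21) and AT2G41090 (3.20) than Col at 9 days and more AT4G19240 (3.85) and AT2G40290 (3.16) at 21 days. It had less AT2G25450 (-5.68), AT5G49440 (-5.58) and AT1G61190 (-4.41) at 9 days, and less AT1G61190 (-5.75), M17 (-4.76) and AT5G49440 (-4.76) at 21 days. Altogether 648 probe sets differed at 9 days (315 higher, 333 lower) and 396 at 21 days (152 and 244). The latter split was 210 and 180 scaled to a trimmed mean, with a shift of all probe sets by 0.13. Over 194 probe sets that separated Ler from Col at both ages, every mutant group lay at the Ler end of an axis from 0 (Col) to 1 (Ler), with positions of 0.987 ± 0.025, 0.994 ± 0.063 and 0.986 ± 0.026 for ago1-10 at 9, 21 and 35 days, 0.954 ± 0.036 and 0.923 ± 0.067 for ago1-11 at 9 and 21 days, and 1.01 ± 0.039 for dcl1-9. The 2 Ler sets at 21 days differed in 125 probe sets (58 higher and 67 lower in the second). AT1G09480 (2.62), AT2G25450 (2.53) and AT1G78820 (2.15) were higher in the second set, and AT2G20870 (-3.23 and -2.89) and AT2G47880 (-2.81) were lower.

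Direct comparison of the alleles put AT2G44120 higher in ago1-11 than in ago1-10 by 6.65 at 9 days (adjusted p = 1.4e-17) and by 6.57 at 21 days. At 9 days AT2G05540 (4.00) and AT2G44140 (3.51) were also higher in ago1-11, and AT1G65500 (-4.02, 37.1 ± 19.5 against 613 ± 370), AT2G43620 (-2.70) and AT4G26365 (-2.45) were lower. At 21 days BGLU28 (3.39) and AT4G29030 (3.18, 367 ± 122 against 42.4 ± 26.2) were higher, and AT5G06730 (-3.66), ChiC (-3.49) and sks16 (-2.76) were lower. The alleles differed in 848 probe sets at 9 days (438 higher, 410 lower in ago1-11) and 448 at 21 days (289 and 159, or 261 and 236 scaled to a trimmed mean). The 21-day count was 60 with only the groups compared and 978 with the ago1-10 arrays grouped by title number.

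The oldest ago1-10 plants, at 35 days, were compared with 21-day ago1-10 plants. Limma called 3 probe sets, all unnamed here. The brightest fell from 430 to 108 (-1.96), another fell from 41.8 to 15.6 (-1.42) and the last rose from 0.803 to 10.9 (2.42), each with an adjusted p of 0.013. At an unadjusted p under 0.05 there were 501. Scaled to a trimmed mean 2 probe sets were higher and 2 lower. No wild type was measured at 35 days, so age and mutation cannot be set apart there. All 21-day ago1-10 arrays carry strain code MR44 and all 35-day ones MR49, so age and strain code cannot be set apart either. The count also rests on the age labels. Of 29 numbered sample titles 27 carry 1 at 9, 2 at 21 and 3 at 35 days, and the other 2 are 21-day replicate 3 (x44-3B) and 35-day replicate 1 (x49-2A). Grouped by the title number instead, the same 6 arrays called 720 probe sets, 377 higher and 343 lower in the arrays numbered 3, so the labelled groups do not show that little changes between these ages.

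The mutants shared part of their changes. At 9 days 169 probe sets changed the same way in ago1-10 and ago1-11 (76 higher, 93 lower), where 23.4 would be shared by independent lists of these sizes. The higher and lower shares were 82 and 67 with quantile normalization. At 21 days the alleles shared 128 (75 higher, 53 lower) against 18.1 by independent lists. Both alleles used the same Ler arrays. With unchanged groups simulated against those arrays (20 draws) the correlation across probe sets was 0.57 at 9 and 0.50 at 21 days beside observed values of 0.56 and 0.68, and the covariance was 0.0761 and 0.0749 beside 0.255 and 0.364. With separate Ler sets for the alleles at 21 days 108 and 234 were shared, where independent lists give 21.0 and 75.1. At 9 days there is no second Ler set. The part of the 9-day overlap that comes from the common Ler arrays could not be taken out in this way.

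With dcl1-9, which had its own wild-type arrays, ago1-10 shared 32 changed probe sets (28 higher, 4 lower) against 4.94 by independent lists. They included ARPN, AT4G33720, AT5G64100, BGLU21, JAL31, JAL34, MSRB5, AT2G39420 and the transcription factor gene NAI1 (1.40 in ago1-10, 1.27 in dcl1-9) among the higher ones, and AAH and AT4G36530 among the lower ones. ago1-11 and dcl1-9 shared 6, all higher, against 0.741, or 8 higher and 1 lower with quantile normalization. Those 6 probe sets were the ones higher in all 3 mutants at 21 days, namely MSRB5, AT2G39420, AT4G33720 and 3 unnamed ones, and 0 were lower in all 3. Between ages ago1-10 shared 348 probe sets (101 higher, 247 lower) against 107 by independent lists, with 26 opposite and a correlation across all probe sets of 0.42. ago1-11 shared 32 against 3.92, with 6 opposite. Its differences at the 2 ages had a correlation of 0.003 across all probe sets, so they showed no general likeness. Its 9-day arrays carry several strain codes and its 21-day arrays only MR57, so age and strain code are mixed there.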

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

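The tests of an accession difference at AT2G44120 and of the choice of wild-type set for dcl1-9, and the grouping by title number, were chosen after the results were seen, and the others were written down before.

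BGLU21 stood out within a group, because replicate 2 of the second Ler set lay at 4.72 on the log2 scale, below the other 3 arrays at 6.99 to 7.43. The gap was 0.840 of the group's range, past the limit for 4 values, in 1 of 76 sets tested where 3.80 would pass by chance. Without that array the dcl1-9 difference of BGLU21 was 1.91 with an adjusted p of 0.203.

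The effect of age differed for 320 probe sets in ago1-10 (175 higher, 145 lower at 21 than at 9 days, relative to Ler). The largest increases were those of AT3G15356 (4.50), AT1G27020 (4.11) and ChiC (3.9), and the largest decreases those of AT2G20870 (-5.0 and -4.98) and AT4G18970 (-3.82). In ago1-11 the age effect differed for 126 probe sets (80 higher, 46 lower, or 59 and 82 scaled to a trimmed mean), with BGLU28 (4.28), AT5G39580 (4.13) and AT1G65500 (3.98) against AT2G20870 (-3.69), AT4G14990 (-3.45) and COR15B (-2.58). Both contrasts use the first Ler set at 21 days. AT2G20870 was higher in that set than in the second. Against the second set its 21-day ago1-11 difference was 0.15 and 0.23, not called. Its age decreases therefore rest in part on the Ler set. Among the 9-day ago1-10 arrays replicate 4 carries strain code MR49 and the others MR44, while all 21-day ones carry MR44. The ago1-11 arrays carry strain codes MR51, MR53, MR54 and MR57 at 9 days but only MR57 at 21 days. The age effect in ago1-11 is therefore not set apart from strain code. The ago1-10 count was 139 with only the groups compared, 185 with plain probe sets and 780 with the arrays grouped by title number. That grouping exchanges 2 arrays and changes the spread shared by all comparisons (dcl1-9 against Ler went from 48 to 73), so the rise cannot be put down to 1 array. The ago1-11 count was 42 with only the groups compared.

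The 21-day effects of ago1-10 and dcl1-9 differed for 136 probe sets (57 higher, 79 lower in ago1-10). AT5G06730 (4.04), AMY1 (3.92) and AT2G42360 (3.76) were higher in ago1-10, and AT2G44120 (-6.21) and AT2G20870 (-4.83 and -4.08) were lower. Those of ago1-11 and dcl1-9 differed for 12 (4 higher, 8 lower), with AT4G33550 (-2.06) and IAGLU (-1.90) the only 1-gene probe sets among them. With only the groups compared the counts were 222 and 24, and with arrays grouped by title number 470 and 19. Each mutant has its own Ler set in these contrasts, and the 2 Ler sets themselves differed in 125 probe sets. AT2G20870 was among the genes lower in the second Ler set than in the first, so its difference here rests in part on the Ler sets.

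AT2G44120 and AT2G44140, consecutive by start position, were far lower on all 10 ago1-10 arrays and at wild-type level in ago1-11 (626 ± 209 for AT2G44120 at 9 days) and dcl1-9 (559 ± 85.3). An accession difference is excluded, since Ler and Col differed there by at most -0.44. Of 13 measured loci within 20 genes on either side 0 were called lower at both ages, against 79 of 2538 (3.11%) elsewhere. At that share 0 of 13 is no departure. The nearest measured loci were AT2G44090 and AT2G44200, at -3 and 10 in gene order from AT2G44120. They stood at 0.03 and -0.36, and at -0.11 and 0.27, at 9 and 21 days, none called, though AT2G44200 is dim. That argues against an altered segment that reaches them, but the other genes between them were not measured. A lesion or insertion in the ago1-10 line, at AT2G44120 and AT2G44140 or over a segment short of those loci, could give the pattern. It was not tested, and nor was an effect of the allele itself.

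Of 24 photosynthesis and chlorophyll genes 18 were called lower in 21-day ago1-10, with a median of -1.27, but the list did not pass camera with an estimated correlation of 0.366 (adjusted p = 0.298). Compression of bright values does not account for the list's median, since 211 other probe sets of like brightness had a median of -0.14. These probe sets were pooled over all members, so the comparison does not cover the few brightest members on their own. Scaling does not account for the list's median, which was at most -1.13 over 4 scalings. It does bear on single members, since with quantile normalization RCA was no longer called. The shorter photosynthesis list fixed beforehand then lost its camera pass (adjusted p = 0.0846). With the second Ler set as wild type 16 of the 24 genes were lower and 2 higher in ago1-10 (median -0.98). Against the first Ler set dcl1-9 had a median of -0.74, so the contrast between these mutants depends on the Ler set. A biological effect of the allele on chloroplast transcripts, or a delay in leaf development, may remain as a hypothesis found in the same data, and neither was tested further.

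In dcl1-9 81.2% of the calls were higher. The arrays were already scaled to a common median, and quantile normalization did not lessen the skew (83.0% higher). As a second scaling it had little difference in brightness left to remove, so it does not exclude brightness as a cause. The array named Ler21 does not account for the skew, since 87.9% were higher without it. The share was 71.4% with 16 added, 73.7% with plain probe sets only and 88.5% scaled to a trimmed mean. The share was 43.2% with the first Ler set as wild type and 54.7% with the spread taken from the groups compared alone. The choice of wild-type set, or of the spread used, may therefore account for the skew, and no biological explanation was tested.

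Other groupings of the same arrays were tested for every comparison of groups. Where 35 groupings exist, only the real one reached its count. The real and highest other counts were 979 and 316 for ago1-10 and 287 and 223 for ago1-11 against Ler at 9 days. Against Col at 9 days they were 1536 and 672, and 698 and 352. They were 848 and 59 for the alleles at 9 days, 48 and 0 for dcl1-9 and 125 and 59 for the Ler sets. Each share of 1 in 35 is under 0.05 but is the smallest that 35 groupings allow. It was not corrected over the comparisons, so chance is not excluded. The Ler sets, of 1 genotype, passed too, so a pass does not set a genotype effect apart from a difference between sets. With 10 groupings a share under 0.05 cannot be reached. The real and the highest other counts were 1315 and 166 for ago1-10 and 170 and 12 for ago1-11 against Ler at 21 days, 1833 and 33 and 718 and 57 against Col, 648 and 1 and 396 and 17 for Ler against Col at 9 and 21 days, and 448 and 148 for the alleles at 21 days. For 35 against 21 days of ago1-10, 3 of the 10 groupings called as many as the real 3. Grouping 35-day replicate 1 with 21-day replicates 1 and 2 called 720 probe sets, which points to a structure of these samples that their age labels do not describe. This split is the one given by the number in the sample titles (x49-2A, x44-2A and x44-2C against x44-3B, x49-3A and x49-3B).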

How the results depend on the processing

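The scalings to a trimmed mean, the pseudocount of 16, the point between digit groups read as a decimal point, the run without 7 arrays and the grouping of ago1-10 arrays by title number were chosen after the data were seen. Of the counts, 149 values under planned and 91 under added alternatives stayed within 1.5 times, and the cause of the rest was not tested, except that plain probe sets test fewer probe sets. Fewer arrays, in a model with only the groups compared or after an omission, leave less power. That cannot account for the counts that rose, such as 285 for dcl1-9. A model with only the groups compared keeps the differences and changes the spread they are judged by. Arrays correlated at 0.9655 to 0.9715 within dcl1-9 and at 0.9511 to 0.9722 within the second Ler set. Within 21-day ago1-11 they correlated at 0.9177 to 0.9382. The spread shared by all groups can therefore be wide for dcl1-9 and narrow for ago1-11, and the order of the counts depends on it. With only the groups compared the counts were 691 (ago1-10 at 21 days), 95 and 70 (ago1-11 at 9 and 21 days), 285 (dcl1-9), 405 (ago1-11 against Col at 21 days), 153 (Ler against Col at 21 days), 63 (the Ler sets), 60 (the alleles at 21 days), 0 (35 against 21 days, where limma with all groups called 3 and 501 had an unadjusted p under 0.05), 139 and 42 (age effects in ago1-10 and ago1-11), 222 and 24 (ago1-10 and ago1-11 against dcl1-9), and 524, 54 and 46 for calls against both wild types (ago1-10 at 21 days, ago1-11 at 9 and 21 days). With plain probe sets only they were 648 and 834 (ago1-10 at 9 and 21 days), 111 (ago1-11 at 21 days), 19 (dcl1-9), 283 (the alleles at 21 days), 185 (age effect in ago1-10), 82 and 6 (ago1-10 and ago1-11 against dcl1-9), and 601, 62 and 66 for calls against both wild types. The ago1-11 against dcl1-9 count of 12 was 20 with quantile normalization, 21 scaled to a trimmed mean and 25 with a pseudocount of 16, which gave 8 for 35 against 21 days. Without a filter the age effect in ago1-11 gave 75 and the 35-day accession position was 1.02. With the point read as a decimal point the Ler sets gave 57, 35 against 21 days 11 and the age effect in ago1-11 46, and these genes reversed: at 9 days in ago1-10 AT4G33720 (-3.95), AT4G16260 (-6.56), OSM34 (-7.05), COR47 (1.76) and KIN2 (5.96), and at 21 days AT1G65500 (-2.02), AT4G16260 (-5.47), AT4G33720 (-2.29), LTI30 (-1.31), OSM34 (-6.52), HPR (4.37), PSAN (7.53) and PSB27 (4.77). With the other Ler set ago1-11 at 21 days gave 705, dcl1-9 gave 336, KIN2 reversed to 1.55 in ago1-10, 1.75 in ago1-11 and -2.02 in dcl1-9, AT2G20870 to 0.15 and 0.23 in ago1-11 and IAA18 to 0.96 in dcl1-9, and ago1-10 and ago1-11 on separate Ler sets shared 234. Strain code MR57 alone gave 154 for 9-day ago1-11, but this is a group of 1 array, so it does not test the code. An estimated correlation left 2 of 10 list tests. Leaving out 1 array at a time gave 562 to 914 and 782 to 1423 for ago1-10 at 9 and 21 days, 85 to 505 and 68 to 273 for ago1-11, and 16 to 50 for dcl1-9. With the label letter or number as a replicate block the counts were 562, 755, 61, 57 and 29, in the order ago1-10 at 9 and 21 days, ago1-11 at 9 and 21 days and dcl1-9. Arrays of the same label did not deviate together (correlations of -0.31 to 0.18), so the labels do not pair the arrays. Of the genes named, 349 values stayed on their side with quantile normalization and 8 lost and 3 gained a call, while with a pseudocount of 1 all 360 stayed. With a replicate block 49 lost and 3 gained a call. With only the groups compared 22 lost and 9 gained one, and without the 7 arrays 23 lost and 5 gained one. With the 21- and 35-day ago1-10 arrays grouped by title number the counts were 73 for dcl1-9, 978 for the alleles at 21 days, 720 for 35 against 21 days, 780 and 235 for the age effects in ago1-10 and ago1-11, 470 and 19 for ago1-10 and ago1-11 against dcl1-9, and 57 and 12 for the calls shared with dcl1-9 by ago1-10 and ago1-11. The 21-day ago1-10 list tests kept their side of the threshold, with 0.0252 for microRNA targets and 0.0053 and 7.3e-13 for photosynthesis. With an estimated correlation the main run gave 0.240, 0.298 and 0.298 for them. Defensin genes passed in 21-day ago1-11 (0.0488), though with an estimated correlation their main run gave 0.298. In 21-day ago1-11 AT2G43590 lost its call (0.0520). Of 48 named calls with a group mean under 12.2, a pseudocount of 16 ended 7, those of SCPL43 in 21-day ago1-10, AT1G12010, UGT73C1 and both AT1G09500 probe sets in 9-day ago1-11, and AT2G22590 and AT2G41800 in dcl1-9. Signal over background limits the dim probe sets, and 6112 of 8247 were tested.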

Other observations

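On the arrays labelled 35 days AT2G44120 averaged 3.28 ± 2.57 and AT2G44140 6.15 ± 4.05 on 3 arrays, close to the 5.39 ± 2.87 and 4.84 ± 3.24 of 21-day ago1-10. ARPN and APS4 averaged 66.1 ± 48.5 and 378 ± 136 at 35 days, beside 16.8 and 119 in the first 21-day Ler set, a comparison across ages that was not tested. The ARPN values were 120, 52.2 and 26.1, so the mean is carried by replicate 1 (x49-2A), whose age label is in doubt, and replicate 3 lay next to the highest array of that Ler set (24.97). The APS4 values were 534, 322 and 279, with 150 the highest in that Ler set. CCS, chosen after its value was seen, stood at -0.10, 0.26, 0.43 and 0.51 in ago1-10 at 9 and 21 days and ago1-11 at 9 and 21 days, none called, beside 1.81 in dcl1-9. At 21 days the difference of effects was -1.55 for ago1-10 (adjusted p = 0.064) and -1.30 for ago1-11 (adjusted p = 0.377) against dcl1-9, neither called. The contrast rests on the second Ler set, where CCS averaged 76.7, since dcl1-9 (261) lay near the first Ler set (217), Col (271), ago1-10 (230) and ago1-11 (274) at 21 days and stood at 0.43, not called, against the first Ler set.

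A hypothesis written before the test was that genes higher in dcl1-9 also tend to be higher in ago1-10, which has other wild-type arrays. Of 39 probe sets called higher in dcl1-9, 36 (92.3%) had a positive ago1-10 difference at 21 days, against 50.6% of the 6073 others (Fisher's exact test, one-sided, p = 3.0e-08), and 28 were called higher in ago1-10. In ago1-11 34 of the 39 (87.2%) were positive. Probe sets are not independent of each other, so the p-value describes these probe sets only, and a shared effect on the microRNA pathway is a candidate explanation that these arrays cannot set apart from a shared growth defect.

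A hypothesis formed after the groupings were seen was that the number in the sample titles, not the age label, groups the 21- and 35-day ago1-10 arrays. Of these 6 arrays 6 correlated best with one of the same title number and 3 with one of the same age. For 21-day replicate 1 the margin was narrow (0.9513 within its age, 0.9509 with 35-day replicate 1, both with the same title number), and before scaling its best match lay at 35 days (0.9511 against 0.9506), which leaves 2 matched by age. The split by title number called 720 probe sets where the split by age called 3. Exchanged age labels of 21-day replicate 3 and 35-day replicate 1 could give this, as the numbers go with the ages on 27 of 29 numbered titles. A batch or harvest that the number marks could give it as well, and no label sets these apart.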
